A study of Homo sapiens with 661 samples.

How the data were processed

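The samples were patient-derived xenografts (PDXs), human tumours grown and passed on in mice, from 371 models with 661 samples. Per the labels, each sample has a model number, a primary site, a passage and a title that names the chain of mice it came through. Passage 0 is the first mouse generation, and mice of later passages were implanted from earlier ones. RNA was amplified with the Nugen Ovation kit, labelled with biotin and hybridised to Affymetrix arrays of human genes, per the labels, with 1 array per sample. There were 127, 205, 32 and 7 models with 1, 2, 3 and 4 samples, and 138, 234, 89, 81, 107 and 12 samples of passages 0 to 5.

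The authors' values were background-corrected, normalised between arrays and summarised per probe set with GCRMA, per the submitters' processing notes, which state no version. The deposited values are on the log2 scale, run from -0.74 to 14.55, and have array medians between 2.51 and 2.68. Nearly all values under 4 lay within 0.0006 of the log2 of a number with 1 decimal, so low values had been rounded on the linear scale. The scanner files were not used here. GCRMA shifts values of dim probe sets to a low floor, and a change there is compressed. Arrays give no read depth, and the number of models limits the precision.

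The table held 54675 probe sets. In the annotation table, 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none, and only those with 1 symbol were used. Gene IDs were looked up in the RefSeq gene table, where 41043 symbols were current and 54 IDs had no match. For each gene the probe set with the highest mean over all arrays was taken, which gave 19721 genes. Genes with a value of at least 5 in at least 20 arrays were kept, 11779 in all. The choice by highest mean can pick a probe set that follows a gene poorly, and the probe sets so chosen for ESR1 and NKX2-1 did not pass the filter. CA9 and TP63 were not analysed here, and some other members of the gene lists are not reported here. Control probe sets, XIST, TSIX and genes of the Y chromosome were left out everywhere.

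Similarity was the Pearson correlation across genes between 2 arrays. Per model, the mean over its own pairs was set against pairs with other models of the same site, and pairs within a site against pairs between sites, with 2-sided sign-flip permutation tests over models of 100000 resamples. For passage gap, passage 0 and lineage, 1 pair per model was used, its earliest and its latest sample. The gap was tested by correlation with permutation, and the other classes by permuting the class within each gap. For these classes the p counts permutations as far from the permutations' mean as the value is, and batches were not kept apart. The comparison of passage 0 pairs had 49 models with such pairs and 134 without, and that of lineage 191 with the same first mouse and 50 without. Within a batch the gap was tested in 231 models, or 118 without and 113 with spike-ins. With passage 0 samples left out it was tested in 162 models, or 153 within a batch. The smallest p these permutations can give is 1e-05. The share of variance between models was the intraclass correlation of a one-way random-effects model per gene, with a bootstrap over models of 100 draws for the interval.

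Passage contrasts were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with the model as a fixed block, on 206 arrays for passage 0 and on 185 for passage 1, and Benjamini-Hochberg adjusted p under 0.05. The pairing comes from the model number in the labels, since samples of 1 model are tumours grown from 1 patient's tissue, and each of 534 samples with a partner had its highest correlation with a sample of its own model. Whether different models can share a patient is not given in the sources used here. Primary sites with at least 10 models were compared on model means, with limma's F-test and with each site against the mean of the other 8 sites at a log2 difference of at least 1. Gene lists were tested with camera at a preset correlation of 0.01, and by the mean shift of the list per model with a sign-flip permutation test. The shifts from passage 0 were compared between sites with at least 10 such models by a permutation test of the F statistic. Lists with fewer than 3 genes past the filter were not tested. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used for the rest.

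The groups, the tests, 31 gene lists and the rule for named genes were set before the data were examined. The rule took, for each passage contrast, up to 12 rises and 12 falls with the largest log2 change among genes past the threshold that moved the same way in at least 70% of the models. It took 3 genes per site by log2 difference, and the 5 highest and 5 lowest variance shares among genes with a mean of at least 7. From each list, the 2 to 4 members with the largest change could be named. Alternatives covered the filter, a further quantile normalisation or median centring of arrays, the block, 1 sample per arm, direct lineage, other probe sets, the trend, RNA quality covariates, the similarity measure and the threshold.

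No scan dates were used here, but the control probe sets split the arrays. Probe sets for Bacillus transcripts, added as labelling controls, had a mean log2 of 7.93 ± 0.743 (SD) on 361 arrays and of 2.19 ± 0.184 on 300, with none between 2.77 and 5.87. All 138 passage 0 arrays were without that signal. The groups were named arrays with and without spike-ins, and treated as a labelling batch. The 3′ minus 5′ signal of ACTB, a measure of RNA integrity and amplification, averaged 3.64 ± 0.637 with spike-ins and 1.38 ± 0.497 without. The site comparison had 142 models without and 219 with spike-ins, and the variance share 118 and 114. Within-batch values, the batch as a term and a test that leaves out models spanning both batches were added after this split had been seen.

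The scripts were tested on simulated data. With 200 of 11779 genes changed, the contrast of passage 0 with later passages recovered 66% of genes changed by 0.25 on the log2 scale, 98% at 0.5 and 100% at 1. The contrast of passage 1 with passages 3 to 5 recovered 72%, 98% and 100%. The simulated site differences of 2 were recovered for 99.5% of 200 genes against the other sites and for 98% with the F-test. Simulated variance shares of 0.3, 0.6 and 0.9 were estimated at 0.299, 0.601 and 0.899. The sign-flip test gave p under 0.05 in 0.0525 of null draws.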

Results

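Expression was measured on 661 Affymetrix arrays of human probe sets, 1 array per tumour, from 371 PDX models. Of these models, 34.2% had 1 sample, 55.3% had 2, 8.63% had 3 and 1.89% had 4, so that 244 models with 534 samples had repeated tumours. The samples came from passage 0 (20.9%), passage 1 (35.4%), passage 2 (13.5%), passage 3 (12.3%), passage 4 (16.2%) and passage 5 (1.82%). The labels gave 19 primary sites, and 9 of them had at least 10 models, with 338 models and 609 samples. These were the large intestine (64 models), lung (50), pancreas (46), soft tissue (41), breast (40), ovary (36), skin (29), kidney (22) and oesophagus (10). Array medians lay between 2.51 and 2.68 on the log2 scale, no 2 arrays were identical, and 11779 genes passed the filter on low values. The arrays fell into 2 groups, 300 without and 361 with the signal of Bacillus spike-in controls, and 23 models had arrays in both. These groups were treated as labelling batches. Mouse tissue in a xenograft was measured only as far as its RNA bound to human probes.

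The first comparison asked how alike tumours of 1 model were, set against other models of the same primary site. Tumours of 1 model had a mean Pearson r across genes of 0.972 ± 0.0156 (SD over 243 models), and the same tumours had 0.817 ± 0.0468 with other models of their site. The difference of 0.156 ± 0.0477 was above 0 in 243 of 243 models (sign-flip permutation test, 2-sided, p = 1e-05, the smallest the permutations can give; adjusted p = 1.5e-05 over 6 tests of similarity). Pancreas and large intestine models were the most alike within a site, with means of 0.865 ± 0.0272 (46 models) and 0.861 ± 0.0317 (64 models). Lung and kidney models were the least alike, with 0.777 ± 0.0298 (50 models) and 0.778 ± 0.0346 (22 models). Within a model, the mean r ranged over the 9 sites from 0.967 ± 0.0183 in breast to 0.979 ± 0.0106 in skin.

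Models of 1 site were also more alike than models of different sites, with a mean r of 0.817 ± 0.0444 within and 0.738 ± 0.0256 between sites. The difference was 0.0795 ± 0.0432 (SD over 338 models), above 0 in 323 of them (sign-flip permutation test, p = 1e-05; adjusted p = 1.5e-05). Soft tissue and skin models were the farthest from the other sites, with means of 0.696 ± 0.0272 and 0.717 ± 0.0151. Every one of the 534 samples with a partner had its highest correlation with a sample of its own model (100%, exact 95% confidence interval 99.3 to 100), while shuffled model labels gave 0.176% on average and 0.749% at most. The smallest margin over the best sample of another model was 0.00267 and the median margin was 0.0773. Of the samples with no partner at the 9 sites, 90 (79.6%) were nearest to a sample of their own site. Within a batch, the difference for models was 0.152 (above 0 in each model with such pairs, p = 1e-05), that for sites was 0.0782 (322 of 338 models, p = 1e-05), and 499 of 499 samples were nearest to their own model. Genes are not independent replicates, and whether samples that failed an identity check had been removed earlier was not examined here.

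**Figure D1:**
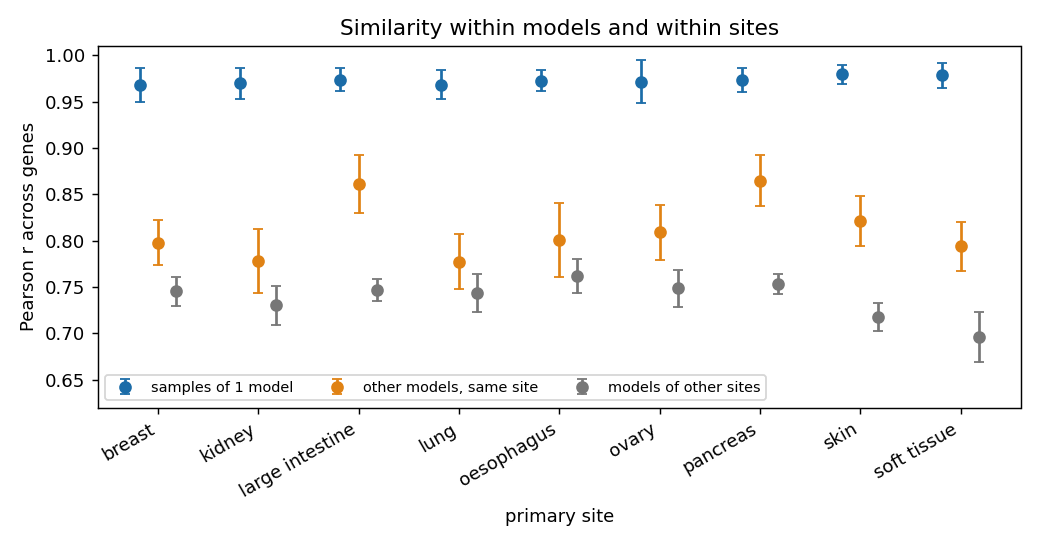
Mean Pearson r across genes (vertical axis, no unit) for each of 9 primary sites, between samples of 1 model (blue), with other models of the site (orange) and with models of other sites (grey). Points are means over models, bars are SDs, and the means within a model lie between 0.967 and 0.979 at every site.

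Genes of the tissue of origin were among those that differed between the 9 primary sites. Skin models had the melanosome protein PMEL 7.21 ± 0.255 (SE) higher on the log2 scale than the mean of the other 8 sites, at a mean of 9.91 ± 3.85 (SD, 29 models). In soft tissue models the collagen gene COL6A3 was 7.29 ± 0.410 higher, at a mean of 10.61 ± 3.12 (41 models). FABP1, the fatty acid-binding protein of liver and gut, was 7.11 ± 0.321 higher in large intestine models, at 9.45 ± 3.52 (64 models). ANXA10, an annexin of gastric epithelium, was 7.14 ± 0.352 higher in pancreas models, at 9.68 ± 3.08 (46 models). Of 11779 genes, 11615 (98.6%) differed between sites (limma's F-test), and there were 6925 calls of a gene higher by at least 1 at 1 site.

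Higher genes numbered 1108 in pancreas, 1098 in soft tissue, 1008 in skin, 925 in large intestine, 739 in kidney, 612 in ovary, 506 in breast, 482 in oesophagus and 447 in lung models. With no filter soft tissue models had more than pancreas models (1131 against 1114), as they did with quantile normalisation (1124 against 1095) and over all probe sets (2188 against 1912). In skin models, MLANA, a melanoma antigen, was 6.96 higher and S100B, a neural crest marker, also 6.96. In large intestine models, the galectin LGALS4 was 6.67 higher and the keratin KRT20 6.46. In pancreas models, lysozyme (LYZ) was 7.01 higher and the protease CTSE 6.87. In soft tissue models, the collagen COL1A2 was 5.97 higher and fibrillin (FBN1) 5.83. In breast models, MGP, a matrix protein that limits calcification, was 6.53 ± 0.471 higher, ELF5, a transcription factor of the mammary gland, 4.46, and EFHD1 4.32. In ovary models, KLHL14 was 5.64 higher, the homeobox gene EMX2 5.52 and the matrix gene SPON1 5.18. In kidney models, POU3F3, a factor of nephron development, was 5.17 ± 0.378 higher, the methyltransferase BHMT2 4.89, and COXFA4L2, a mitochondrial gene induced by hypoxia, 4.86. In lung models, the transcription factor SOX2 was 4.45 ± 0.394 higher, and the calcium-binding proteins S100A8 and S100A9 were 4.35 and 4.22 higher. In oesophagus models, PLAC8 was 4.73 higher, the chloride channel ANO1 4.50 ± 0.705 and LYZ 4.45 ± 0.882. Among these 27 pairs of gene and site, PLAC8 and LYZ of the oesophagus had a higher mean at another site, since in the pancreas their means were 8.75 and 11.44, against 8.54 and 9.17 in the oesophagus. Pancreas models were also close behind for LGALS4, at 10.23 against 10.92 in the large intestine, and for ANO1, at 8.02 against 8.71 in the oesophagus.

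Among the lists of cell type genes, all 9 melanocyte genes were higher in skin models, with the transcription factor SOX10 at 5.62 and TYR, the enzyme of melanin synthesis, at 6.15. All 11 intestinal epithelium genes were higher in large intestine models, with the intestinal transcription factors CDX1 at 3.50 and CDX2 at 3.13. The 11 genes of gastric and pancreatic duct were higher in pancreas models (TFF1, a secreted mucosal peptide, 6.86), and 10 of 11 in oesophagus models. All 16 fibroblast genes were higher in soft tissue models, with LUM at 5.20. Of 10 Mullerian epithelium genes, 9 were higher in ovary models, with SOX17 at 4.62 and PAX8 at 2.80. All 6 kidney genes were higher in kidney models, with the nephron factor PAX2 at 2.11, and 6 of 8 mammary genes were higher in breast models, with GATA3 at 3.78. In lung models, 7 of 7 squamous epithelium genes were higher, with the basal keratin KRT5 at 3.93, while 0 of the 3 lung epithelium genes tested, out of 9 in the list, passed the threshold. In oesophagus models 0 of 7 squamous epithelium genes were higher, and 2 adjusted over the list alone. Epithelial state genes were higher in large intestine (11 of 11), pancreas (10 of 11) and oesophagus models (10 of 11, and 11 adjusted over the list alone), and fewer were in breast (6), ovary (5) and lung models (4). The same 11 genes were lower in soft tissue models (11 of 11) and skin models (10 of 11), with the adhesion protein EPCAM at -6.89 and -6.13, and in kidney models 5 were lower and 0 higher. In these site lists, the counts adjusted over the list alone were the same as those over all genes unless both are given.

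Pathway lists differed between sites too. In kidney models, 9 of 12 hypoxia genes were higher, with ANGPTL4, a lipase inhibitor, at 4.40 ± 0.302 and VEGFA, the angiogenic factor, at 1.58, and 0 were lower. MHC class II genes, which present antigen, were higher in kidney models (6 of 8, CD74 at 2.46 ± 0.463), and 4 of 8 were lower in soft tissue models (CD74 at -2.32). Ovary (3), pancreas (2) and skin models (1) also had higher class II genes, and skin (2) and large intestine models (1) lower ones. Interferon response genes were higher in ovary models (10 of 12, IFIT1 at 2.31 ± 0.395), and lower in skin (7 of 12), large intestine (5), lung (4), soft tissue (3) and breast models (1, and 0 adjusted over the list alone). The large intestine (2), pancreas (3) and soft tissue (2) also had higher interferon genes, with IFI27 at 1.97 and 3.07 in the first 2 and IFI44 at 1.42 in soft tissue.

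Within the batches, 9707 genes differed between sites on arrays without spike-ins and 11116 on arrays with them, with 5379 and 6865 calls of a gene higher at 1 site. By site, the higher genes without and with spike-ins numbered 20 and 538 in oesophagus, 408 and 847 in kidney, 667 and 1006 in soft tissue and 614 and 440 in breast models, and ovary models also had fewer without them. The order of the sites thus changed with the batch, in which oesophagus, ovary and soft tissue had 4, 3 and 3 models without spike-ins. PMEL was 9.48 and 6.65 higher in skin models without and with spike-ins, and FABP1 was 8.11 and 6.52 higher in large intestine models. All 27 pairs of gene and site were higher in both batches, and the calls of PLAC8 (4.27, adjusted p = 0.122), ANO1 (4.07, adjusted p = 0.125) and LYZ (2.57, adjusted p = 0.604) in the oesophagus were lost on arrays without spike-ins, where that site had 4 models. With spike-ins, 10 interferon genes were higher in ovary and 6 MHC class II genes in kidney models (33 and 12 models), and without them 0 and 0 passed (3 and 10 models). In oesophagus models, 9 epithelial state genes and 9 of gastric and pancreatic duct were higher with spike-ins, and 0 and 0 without them.

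The share of a gene's variance that lay between models was large for epithelial genes. Among genes with a mean of at least 7, the highest share was that of SLC38A1, a glutamine transporter, at 0.982. Next came EPCAM at 0.981, MAL2, a protein of apical transport, at 0.980, the protease inhibitor SPINT2 at 0.980, and ESRP1, an epithelial splicing factor, at 0.978. Over 11779 genes and 244 models the median share was 0.852 (95% bootstrap interval 0.840 to 0.863), with 2741 genes at 0.9 or more and 73 under 0.5. Among 3532 genes with a mean of at least 7, the lowest shares were those of the embryonic globin HBE1 (0.318), SLC35E1 (0.329), DLGAP4 (0.338), SLC35D4 (0.338) and TSR1, a ribosome maturation factor (0.339). The probe set of HBE1 averaged 9.45 over all arrays, and whether it measured the human gene was not tested. HBE1 had an SD within models of 1.48 and between model means of 1.45. For EPCAM these were 0.508 and 3.73, and for TSR1 0.511 and 0.505. The 2 shares thus differed through the spread between models, and EPCAM was hardly steadier within a model than TSR1. By list, the median share was highest for epithelial state (0.966), intestinal epithelium (0.955) and gastric and pancreatic duct genes (0.950). It was lowest for lung epithelium (0.753), cell cycle (0.795) and ribosomal protein genes (0.804), and fibroblast genes had 0.892. Within batches, the median share over all genes was 0.838 without spike-ins and 0.878 with them, while TSR1 had 0.0688 and 0.397 and SLC35E1 0.156 and 0.516.

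**Figure D2:**
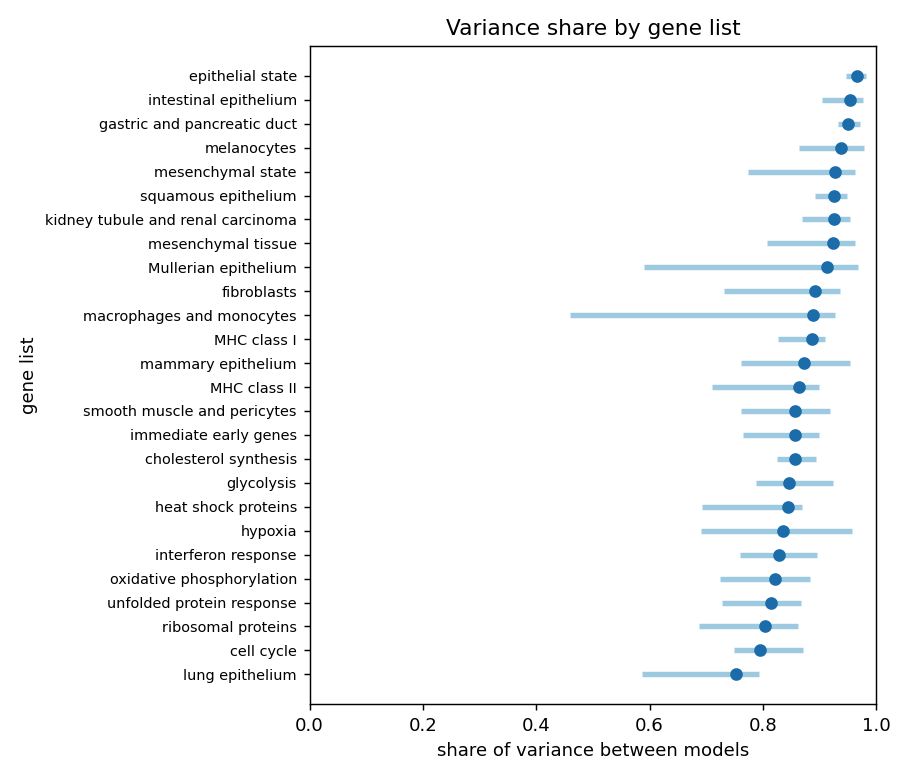
Share of variance between models of all primary sites, differences between sites included (horizontal axis, 0 to 1), for the 26 gene lists. Points are medians over a list's genes and lines run from its lowest to its highest gene; the medians run from 0.753 for lung epithelium to 0.966 for epithelial state.

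The next comparison asked whether tumours of 1 model grew less alike with more passages between them, with 1 pair per model. Pairs of the same passage had a mean r of 0.977 ± 0.0107 (SD, 23 models), pairs 1 passage apart 0.973 ± 0.0170 (67), 2 apart 0.978 ± 0.0109 (67), 3 apart 0.969 ± 0.0154 (49), 4 apart 0.953 ± 0.0187 (35) and 5 apart 0.957 (2). Similarity fell with the gap over 243 models, with a Spearman rho of -0.360 and a Pearson r of -0.380 (permutation tests, p = 1e-05 each; adjusted p = 1.5e-05). Without the 2 pairs with the most extreme gaps, r was -0.374 and rho was -0.349. All pairs 4 or 5 passages apart included a passage 0 tumour, and pairs without one had means of 0.980, 0.974, 0.980 and 0.970 at gaps of 0 to 3. With passage 0 samples left out, rho was -0.252 (p = 0.0014) and r -0.175 (p = 0.0260), and over pairs of 1 batch among these rho was -0.195 (p = 0.0159) and r -0.108 (p = 0.181). Pairs from different batches had a mean of 0.948 ± 0.0147 (23 models) and pairs of 1 batch 0.974 ± 0.0154 (220), and within a gap the difference was -0.0170 (21 models with pairs from different batches, permutation test, p = 0.00221). Over pairs of 1 batch, rho was -0.253 (p = 0.00015) and r -0.270 (p = 3e-05). On arrays without spike-ins rho was -0.471 (p = 1e-05), and on arrays with them -0.143 (p = 0.131). The lowest r of any pair of 1 model was 0.908, above the mean of 0.817 for other models of a site. Samples with a partner reached an r of up to 0.975 with a sample of another model, so the 2 ranges overlapped.

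**Figure D3:**
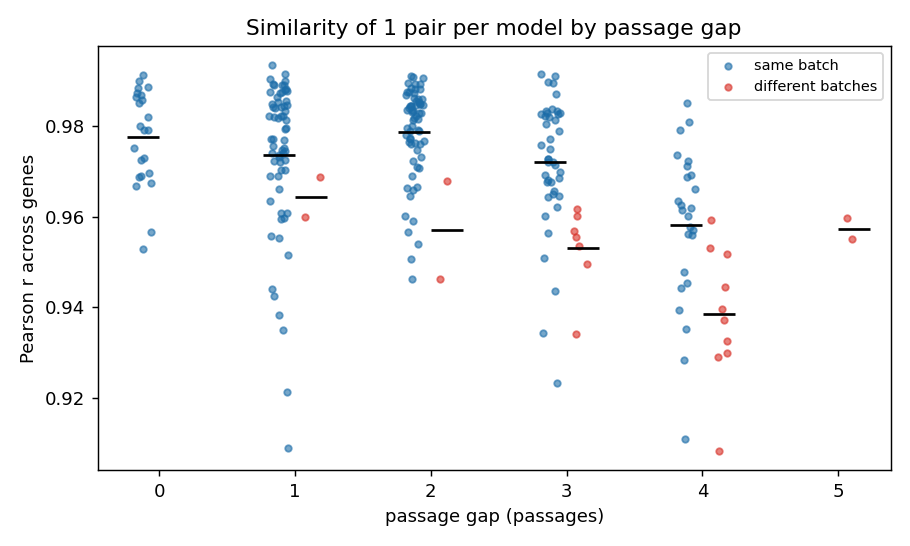
Pearson r across genes (vertical axis, no unit) of 1 pair of samples per model by the number of passages between them (horizontal axis), for pairs of 1 batch (blue) and from different batches (red), with lines at the means. Pairs of 1 batch had means of 0.977, 0.974, 0.979, 0.972 and 0.958 at gaps of 0 to 4.

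Pairs that included a passage 0 tumour were compared with later pairs at the same gap, over gaps of 1 to 3 passages. They had a mean r of 0.970 ± 0.0124 (SD, 49 models) against 0.976 ± 0.0155, a difference of -0.00571 (permutation test within gaps, p = 0.0427; adjusted p = 0.0427). Taken within each gap, the difference was -0.00626 (p = 0.0114). Over pairs of 1 batch, with both batches pooled, it was -0.00512 (p = 0.0783), and -0.00517 when also taken within each gap (p = 0.0317). On arrays without spike-ins it was 0.00218 with the opposite sign (51 against 17 models, p = 0.588), or 0.00192 within each gap (p = 0.634). Tumours from the same first mouse had a mean r of 0.973 ± 0.0167 (SD) against 0.966 ± 0.0174 (50 models) for tumours from different first mice, a difference of 0.00608 (p = 0.00678; adjusted p = 0.00814). Taken within each gap, that difference was 0.0103 (p = 0.00058). Over pairs of 1 batch, with both batches pooled, it was 0.00411 (p = 0.0205), and 0.00789 when also taken within each gap (p = 0.0132). Most of these pairs from different first mice were on arrays without spike-ins, and most from the same first mouse on arrays with them. Mean r within a model was 0.971 without and 0.977 with spike-ins, so the values over both batches do not separate lineage from the batch. On arrays without spike-ins the lineage difference was -0.00108 (p = 0.0715), or 0.00589 within each gap (p = 0.0513). On arrays with them it was 0.00936 (28 against 3 models, p = 0.431). These differences are smaller than the SD of either class.

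Passage 0 tumours were compared with later tumours of the same 86 models, to ask what changes once a tumour has been passed from mouse to mouse. KMT2A, a histone methyltransferase, rose by 0.39 ± 0.0609 (SE) on the log2 scale (adjusted p = 2.07e-05, up in 63 of 86 models), and KIF18B, a mitotic kinesin, by 0.47 ± 0.0983 (adjusted p = 0.00117, 61 of 86). E2F3, a transcription factor of the cell cycle, rose by 0.35 ± 0.0699 (adjusted p = 0.000622, 64 of 86), and hexokinase HK2, the first enzyme of glycolysis, by 0.32 ± 0.0816 (adjusted p = 0.00557, 61 of 86). The largest rises by the rule were those of MEX3D, an RNA-binding protein, by 0.53 ± 0.112, and UTP20, of ribosome assembly, by 0.48 ± 0.0950. BORCS5, of lysosome transport, rose by 0.45, CAPS2 by 0.36, INTS2, of the Integrator complex, by 0.35, FAM168A and TBC1D24 by 0.34 and the transcription factor RFX7 by 0.33.

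Among the falls, DDA1, a ubiquitin ligase subunit, fell by 0.43 ± 0.0912 (adjusted p = 0.00117, down in 64 of 86 models). ID1, an inhibitor of differentiation factors, fell by 0.41 ± 0.102 (adjusted p = 0.00459, 61 of 86), and CLPTM1 fell by 0.31 ± 0.0557 (adjusted p = 0.000227, 65 of 86). SFRP4, a secreted inhibitor of Wnt signalling, fell by 0.22 ± 0.0457 (adjusted p = 0.000873, 61 of 86). BLOC1S1 and the MHC class I pseudogene HLA-J fell by 0.37, TMEM139 fell by 0.35, GOSR2, a Golgi SNARE, fell by 0.34, NIT1 fell by 0.31, TOLLIP and cochlin (COCH) fell by 0.30, and TMEM50B fell by 0.25. BORCS5, CAPS2 and SFRP4 had passage 0 means of 2.89, 2.47 and 2.98, near the floor of the scale. In all, 1483 genes passed the threshold in limma, 1064 rises and 419 falls (71.7% rises). A further quantile normalisation gave 716 rises and 636 falls (52.96%), and median centring 538 and 872 (38.2%), so the balance of rises and falls depended on the scaling. With no filter there were 1079 rises and 977 falls (52.5%).

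Fibroblast genes had 3 falls and 0 rises among 16 genes, and 4 falls adjusted over the list alone. The collagen-binding LUM fell by 0.67 ± 0.190 (adjusted p = 0.0119), COL6A3 fell by 0.52 ± 0.154 (adjusted p = 0.0156) and THY1, a surface protein of fibroblasts, fell by 0.26 ± 0.0735 (adjusted p = 0.0128). The list's mean was -0.19 (camera, adjusted p = 0.0035 over 52 tests of 26 lists), and adjusted p = 0.548 with an estimated correlation. Per model, the mean shift was -0.193 ± 0.608 (SD), down in 51 of 86 models (sign-flip permutation test, adjusted p = 0.0892).

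Intestinal epithelium genes had 2 falls and 0 rises among 11 genes, and 3 falls adjusted over the list alone. KRT20 fell by 0.37 ± 0.122 (adjusted p = 0.0279) and villin (VIL1) fell by 0.19 ± 0.0618 (adjusted p = 0.0310). The list's mean was -0.15 (camera, adjusted p = 0.0035, and adjusted p = 0.548 with an estimated correlation). In the sign-flip test over models this list passed, at -0.148 ± 0.359 (SD), down in 57 of 86 models (adjusted p = 0.00884), as the only one of the lists tested with the filter. On arrays without spike-ins it did not pass, at -0.0945 ± 0.342 (SD, 76 models, adjusted p = 0.308). With no filter, endothelium and T and NK cell genes passed that test as well (adjusted p = 0.00124 and 0.00393), but all except 2 genes of each list had failed the filter on low values, and no change is read from them.

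MHC class II genes had 1 fall and 0 rises among 8 genes, and 3 falls adjusted over the list alone, with CD74, the invariant chain, which fell by 0.46 ± 0.148 (adjusted p = 0.0270). The list's mean was -0.24 (camera, adjusted p = 0.00756, and adjusted p = 0.548 with an estimated correlation). MHC class I genes had 2 falls among 9, the same adjusted over the list alone, since HLA-B fell by 0.25 ± 0.0884 and HLA-C fell by 0.23 ± 0.0822 (adjusted p = 0.0486 and 0.0477). The class I mean was -0.11 (camera, adjusted p = 0.0469, and adjusted p = 0.564 with an estimated correlation). None of 12 oxidative phosphorylation genes passed, alone or over all genes, at a mean of -0.051 (camera, adjusted p = 0.0388, and adjusted p = 0.564 with an estimated correlation). The other 21 lists had adjusted p from 0.0661 to 0.743. The shift of each list was also compared between breast (16 models), large intestine (17), lung (21) and pancreas (14) with a permutation test of the F statistic. Of 26 lists 0 passed, with a lowest adjusted p of 0.359, and 1, Mullerian epithelium, had an unadjusted p under 0.05 (p = 0.0472, with -0.138 in breast and 0.186 in large intestine models); on arrays without spike-ins the lowest adjusted p was 0.618.

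The number of called genes depended on which arrays were used. On arrays without spike-ins alone (76 models) 83 genes passed, 63 up and 20 down, and 72 of them were among the 1483. KMT2A was 0.30 higher there (adjusted p = 0.0115), KIF18B 0.37 (0.0416) and RFX7 0.29 (0.0392), and CLPTM1 was at -0.19, SFRP4 at -0.18 and GOSR2 at -0.25 (0.0416 each). HK2 was at 0.29 (0.0933), E2F3 at 0.20 (0.0984), MEX3D at 0.30 (0.122), ID1 at -0.30 (0.159) and DDA1 at -0.13 (0.286), all past the threshold only with both batches. The 6 genes from KMT2A to GOSR2 were the only named genes that passed there, and all the other named rises and falls lost the call. On the same arrays fibroblast genes had a mean of -0.17 (camera, adjusted p = 0.00191, LUM at -0.67 with adjusted p = 0.0877), intestinal epithelium genes -0.096 (adjusted p = 0.0148), MHC class II genes -0.089 (adjusted p = 0.175) and MHC class I genes -0.030 (adjusted p = 0.375). Glycolysis genes had a mean of 0.097 there (adjusted p = 0.00513), against -0.025 with both batches (adjusted p = 0.468). In the sign-flip test over the 76 models, fibroblast, intestinal epithelium and glycolysis genes did not pass (adjusted p = 0.308 each), and camera with an estimated correlation was not run on these arrays alone. The batch as a term left 71 genes, 59 of them among the 1483. The 3′ minus 5′ signal of ACTB was 0.378 ± 0.872 (SD) higher in later than in passage 0 tumours over 86 models and 0.0548 ± 0.508 over the 76 on arrays without spike-ins. With the 3′ minus 5′ signals of ACTB and GAPDH as covariates limma called 0 genes, with 1124 at an unadjusted p under 0.05 against 3335 without them.

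**Figure D4:**
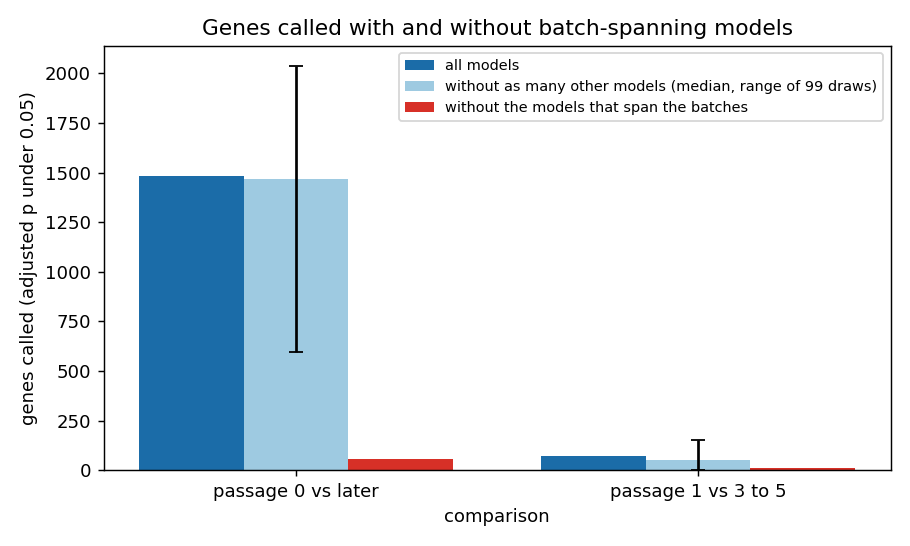
Number of genes called by limma (vertical axis) in each passage comparison with all models (dark blue), without as many other models (light blue, median of 99 draws with a line from lowest to highest) and without the models that span both batches (red). The counts with all models were 1483 and 71, and without the models that span both batches 57 and 9.

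Passage 1 tumours were compared with tumours of passages 3 to 5 from the same 90 models. MDM2, the ubiquitin ligase that holds p53 down, rose by 0.25 ± 0.0441 (SE; adjusted p = 0.00126, up in 64 of 90 models). UNG, a DNA repair glycosylase, rose by 0.26 ± 0.0518 (adjusted p = 0.00801, 67 of 90), and CCNA2, the cyclin of DNA synthesis, by 0.23 ± 0.0540 (adjusted p = 0.0274, 63 of 90). APPL2, an adaptor of endosomes, fell by 0.51 ± 0.0832 (adjusted p = 0.000168, down in 65 of 90). In all, 71 genes passed, 54 rises and 17 falls (76.1% rises), while median centring gave 10 rises and 10 falls (50%), quantile normalisation 31 and 18 (63.3%) and no filter 26 and 14 (65%).

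The rule named 11 rises and 1 fall. BCOR, a corepressor, rose by 0.26, the nuclear import factor KPNB1 by 0.19, the chromatin remodelling subunit BAZ1A by 0.18, and ACLY, which makes acetyl-CoA for lipid synthesis, by 0.16. The translation factor EIF1AX and the phosphatase subunit PPP4R3A also rose by 0.16, the histone chaperone NAP1L1 rose by 0.14 and ERH by 0.11. Of 20 cell cycle genes, 1 rose (CCNA2) and 0 fell, and 2 rose adjusted over the list alone. The list's mean was 0.084 (camera, adjusted p = 0.0035, and adjusted p = 0.564 with an estimated correlation), and per model it was 0.0906 ± 0.490 (SD), up in 52 of 90 models (sign-flip permutation test, adjusted p = 0.334). MHC class II genes had 1 fall among 8, and 2 adjusted over the list alone, with HLA-DRB1, an antigen-presenting chain, which fell by 0.66 ± 0.141 (adjusted p = 0.0129). That list's mean was -0.13 (camera, adjusted p = 0.0446, and adjusted p = 0.548 with an estimated correlation). None of 11 intestinal epithelium genes passed, alone or over all genes, at a mean of -0.084 (camera, adjusted p = 0.0192, and adjusted p = 0.548 with an estimated correlation). The other 23 lists had adjusted p from 0.0559 to 0.785. For epithelial state genes the mean was 0.0019 and the direction of camera was down, and for melanocyte genes the mean was -0.0061 and the median 0.0029.

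On arrays with spike-ins alone (66 models), 21 genes passed, 8 up and 13 down, and 6 of them were among the 71. MDM2 (0.23, adjusted p = 0.0184), ACLY (0.18, adjusted p = 0.0374), ERH (0.12, adjusted p = 0.0331) and APPL2 (-0.44, adjusted p = 0.0184) were among them. UNG was at 0.16 there (adjusted p = 0.165) and CCNA2 at 0.23 (adjusted p = 0.0645). Of the genes named for this comparison, 4 passed there and 8 did not, with BCOR, KPNB1, BAZ1A, EIF1AX, PPP4R3A and NAP1L1 also among the 8. Cell cycle genes had a mean of 0.12 (camera, adjusted p = 1.29e-07) and oxidative phosphorylation genes 0.049 (adjusted p = 0.000145), but neither passed the sign-flip test over the 66 models (adjusted p = 0.321 and 0.162), and an estimated correlation was not used on these arrays alone. In camera, MHC class II genes had -0.052 (adjusted p = 0.890) and intestinal epithelium genes -0.073 (adjusted p = 0.351). On arrays without spike-ins (16 models) limma called 0 genes, with 1222 at an unadjusted p under 0.05, and cell cycle genes had a mean of 0.067 with the direction of camera down (adjusted p = 0.915). The batch as a term left 5 genes, 3 of them among the 71. The ACTB 3′ minus 5′ signal was 0.333 ± 0.977 (SD) higher at the later passages over the 90 models, 0.0632 ± 0.767 on arrays with spike-ins and 0.341 ± 0.826 on arrays without. With both 3′ minus 5′ signals as covariates limma called 0 genes, with 1000 at an unadjusted p under 0.05 against 1727 without them.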

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

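The tests that left out models spanning both batches, and the correlation over pairs of 1 batch, were chosen after the results had been seen, as was the split of arrays by spike-in signal. The 10 oesophagus models were examined for a model apart from the rest at 3 genes, PLAC8, ANO1 and LYZ, and 1 gene stood out. This was ANO1, where the gap between the extreme model and its nearest neighbour was 0.588 of the whole range. Chance passes the limit used for such a gap in about 1 in 20 tests, and the 3 tests shared the same models. A signal of Bacillus spike-in controls, outside the genes compared, was present on 361 arrays and absent on 300.

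The number of genes called between passage 0 and later passages may stem from the labelling batch, since without the 16 models whose arrays span both batches 57 genes were called, against 594 to 2036 (median 1466) in 99 draws that left out 16 other models. Across genes, the correlation of the changes with the batch difference of 7 other models was 0.667 with all models and 0.141 without the 16. The draws were matched for the number of models and not for passage gap. With 1 pair per model, 10 of 23 pairs from different batches were 4 passages apart, against 25 of 220 pairs of 1 batch. Between batches within models 6465 genes were called, and 1840 with the passage number as a term. Neither the drop to 57 nor the correlation thus separates the batch from passage. The share of the 1483 genes that kept their direction on arrays without spike-ins was 98.04%, which a criterion set in advance took as evidence against the batch, but that criterion was wrong because the fit shares 76 of 86 models with the full one and its outcome was close to fixed. RNA quality also stays open, as 0% of the genes were called again with the 3′ minus 5′ signals in the fit, and KMT2A went from 0.39 ± 0.0609 to 0.24 ± 0.0536 (adjusted p = 0.0685), so the call ended through a smaller change at a like SE; these signals follow the batch, and the 2 causes cannot be told apart across batches. Passage itself stays open too, untested apart from these, with 83 genes called on arrays without spike-ins and 0 there with the 3′ minus 5′ signals (1103 at an unadjusted p under 0.05), while chance was excluded, since only 1 of 100 splits within models, the real one, called as many as 1483 and the highest other called 0.

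For passage 1 against passages 3 to 5 the same 2 technical causes may hold, since without the 10 models that span both batches 9 genes were called, against a median of 51 in 99 draws without 10 other models, and 1 draw gave as few. The correlation with the batch difference of 13 other models went from 0.528 to -0.0702. These draws were not matched for passage gap either, so the values do not separate the batch from passage. All of the 71 genes (100%) kept their direction with the batch as a term, a criterion set in advance against the batch that was wrong for the same reason, as both fits use the same arrays. With the 3′ minus 5′ signals in the fit 0% were called again, and MDM2 went from 0.25 ± 0.0441 to 0.20 ± 0.0467 (adjusted p = 0.0855), so that a smaller change ended the call and RNA quality stays open. Passage stays open as well, with 21 genes called on arrays with spike-ins alone, and chance was excluded, since only 1 of 100 splits, the real one, called as many as 71 and the highest other called 1.

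The lower similarity at wider passage gaps may stem in part from the labelling batch, as pairs from different batches were less alike within a gap by 0.0170 in size (a difference of -0.0170, p = 0.00221). Over pairs of 1 batch rho was -0.253 (permutation p = 0.00015), past the bound of -0.05 set for the test. That value pools 2 batches with unlike mean r within a model, 0.971 without and 0.977 with spike-ins, so it cannot exclude the batch. On arrays without spike-ins alone rho was -0.471 (permutation p = 1e-05). The spike-in split does not vary on those arrays, so it is not the cause of the fall there. RNA quality was not tested for similarity. On those arrays the 3′ minus 5′ signal of ACTB averaged 1.28 at passage 0 and 1.73 at passage 4, over partly different models. On arrays with spike-ins alone rho was -0.143 (p = 0.131), and whether the 2 batches differ in this was not tested. Passage, and the time between tumours that comes with it, stays open, as does a difference in processing within a batch, and neither was tested.

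Chance was also excluded for the primary sites. Only 1 of 100 splits of models over sites, the real one, gave as many as 11615 genes that differ, and the highest other gave 10. For calls of a gene higher at 1 site, summed over the sites, only 1 of 100 splits gave as many as 6925, and the highest other gave 77.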

How the results depend on the processing

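The alternatives by spike-in batch, the gap without passage 0 samples, the differences taken within each gap and, for gene lists, no filter were chosen after seeing the data. The differences in similarity within a model (0.0921 to 0.612) and within a primary site (0.0449 to 0.319) kept direction and threshold under all alternatives run for them, and similarity with passage gap kept both in Spearman's rho (-0.471 to -0.195) except on arrays with spike-ins (-0.143, p = 0.131). Pearson's r lost the threshold there (-0.0690, p = 0.470) and over pairs of 1 batch without passage 0 samples (-0.108, p = 0.181). Where no cause is given below, the cause was not tested. Arrays limit what can be seen by signal over background, and values near the floor of GCRMA are compressed.

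The share of samples nearest to their own model was 99.1% with the 1000 most variable genes. The difference for pairs with passage 0 was -0.00830 with those genes (p = 0.355) and -0.0235 on values centred per gene (p = 0.0564). Over pairs of 1 batch, with both batches pooled, it was -0.00512 (p = 0.0783), or -0.00517 within each gap (p = 0.0317). These pooled values do not separate passage 0 from the batch. The difference was of the opposite sign on arrays without spike-ins, at 0.00218, or 0.00192 within each gap. The difference for lineage was 0.0107 with the 1000 genes (p = 0.119) and 0.00936 on arrays with spike-ins, also within each gap. On arrays without them it was -0.00108 pooled over gaps, or 0.00589 within each gap (p = 0.0513). For lineage too, values that pool both batches do not separate it from the batch. Over pairs of 1 batch from both batches, 19 from different first mice and 4 from the same one had a gap of 0. The median variance share was 0.797 with no filter, 0.865 without passage 0, 0.838 on arrays without and 0.878 on arrays with spike-ins.

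Passage 0 against later passages gave 1055 to 2056 genes with other filters, scalings, trends, 1 sample per arm or the replicate block by consensus correlation (1696). It gave 1 gene with no replicate block, since differences between models then count as noise (590 at an unadjusted p under 0.05). It gave 485 in direct lineage (70 models) and 965 without the primary site with most models (65 models). Over all probe sets it gave 4795 of 24140, and with passage as a linear trend 3864 genes. It gave 0 at an adjusted p under 0.01 with a log2 change of at least 1 (3335 at an unadjusted p under 0.05), 0 with 3′ minus 5′ covariates (1124 at an unadjusted p under 0.05), 71 with the batch as a term, 83 on arrays without spike-ins and 0 there with the covariates (1103).

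Passage 1 against passages 3 to 5 gave 40 genes with no filter, 20 with median centring, 0 with no replicate block (49 at an unadjusted p under 0.05), 2.3e+02 (1.93% of the genes tested) with the replicate block by consensus correlation, 28 in direct lineage, 584 of 24140 probe sets and 459 with a linear trend. It gave 0 at the stricter threshold (1727 at an unadjusted p under 0.05), 0 with covariates (1000 at an unadjusted p under 0.05), 5 with the batch as a term, 21 on arrays with spike-ins, 0 on arrays without (1222) and 0 there with covariates (887). Of the results for named passage genes under the alternatives, 348 kept direction and threshold, 2 turned and the others kept the direction alone. These were ERH, at -0.0016 on arrays without spike-ins and APPL2, at 0.064 there with covariates.

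Genes that differ between sites numbered 17886 with no filter and 6361 with a stricter one, through the number of genes tested, and 23788 over all probe sets. Calls of a gene higher at 1 site, summed over the sites, numbered 4093 with the stricter filter, and calls of a probe set 12761 over all probe sets. For named site genes all results kept direction and threshold except 3, which kept the direction alone.

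Of 8 gene list calls with passage, 0 remained with an estimated correlation in camera (3 of 52 tests at an unadjusted p under 0.05), and there were 4 calls with quantile normalisation, 1 with no filter and 3 on arrays with spike-ins. The mean of glycolysis genes turned from below to above 0 at passage 0 against later passages with the batch as a term (0.10) and on arrays without spike-ins (0.097), and at passage 1 against passages 3 to 5 with the batch as a term (0.035), on arrays without (0.17) and with spike-ins (0.00061). With 1 sample per arm 8 calls were made, with the batch as a term 7 and on arrays without spike-ins 6. The sign-flip call of intestinal epithelium genes was kept with 1 sample per arm (adjusted p = 0.00208) and with no filter (0.00393), and was lost on arrays without spike-ins (adjusted p = 0.308).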

Other observations

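Most genes of human immune cells were near the floor in these tumours. The lists of T and NK cells and of B and plasma cells had 2 genes each past the filter and were tested only with no filter (camera, adjusted p = 0.0554 and 0.160 for passage 0 against later passages). With no filter T and NK cell genes passed the sign-flip test over models (adjusted p = 0.00393) and B and plasma cell genes did not (adjusted p = 0.0733), but most of these values lay near the floor, and no change is read from them. The 3 macrophage and monocyte genes had adjusted p = 0.256 for passage 0 against later passages and 0.278 for passage 1 against passages 3 to 5 (camera). CD3D, a T cell receptor subunit, reached a log2 value of 5 on 2 passage 0 arrays and on 4 of 523 later arrays, and CD3E on 0 and 0. CD2, a T cell adhesion protein, reached it on 2 and 0, the cytotoxic co-receptor CD8A on 2 and 1, and LCK, a T cell kinase that some tumours also express, on 24 and 52. The macrophage genes CSF1R and MS4A4A reached it on 0 and 0, CD163 on 0 and 1, C1QA on 0 and 1, and CD14 on 9 and 23. AIF1, a macrophage gene past the filter, reached it on 17.4% of passage 0 and 19.1% of later arrays. LYZ, a macrophage gene that gastric and pancreatic duct cells also express, reached it on 45.7% and 35.4% of them. The B cell gene MS4A1 reached it on 3 and 9 arrays, and 11 arrays had a value of at least 9, while CD79B reached it on 0 and 0. IGHG1, an immunoglobulin heavy chain, reached it on 26 and 63 arrays, and POU2AF1, a B cell coactivator, on 12 and 28.

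Most genes of vessels, fat and red blood cells were low as well, with 2, 2 and 1 past the filter, and their lists were tested only with no filter. Endothelium genes then passed the sign-flip test for passage 0 against later passages (adjusted p = 0.00124; camera, adjusted p = 0.0554), and fat and red blood cell genes did not (adjusted p = 0.0733 and 0.792). Most of these values lay near the floor, no test of them was run within a batch, and no change is read from them. TEK, an angiopoietin receptor, reached a log2 value of 5 on 0 arrays of either kind, CDH5, an endothelial cadherin, on 0 and 2, VWF, the clotting factor of endothelium, on 2 and 6, and PECAM1 on 11 and 35. The fat cell genes PLIN1 and PLIN4 reached it on 0 and 0, and FABP4 on 11 and 32. The globin HBB reached it on 21 and 64 arrays, and ALAS2, of haem synthesis in red cells, on 0 and 0. Fibroblast genes ranged widely, with COL3A1 on 92.8% and 97.5% of arrays, COL1A1 on 65.2% and 74.4%, DCN on 10.1% and 17.4% and PDGFRB on 1.45% and 8.99%. All of these counts and shares are over every array of passage 0 and every later array, which came from different models and sites, so they do not compare passages within a model. Smooth muscle and pericyte genes, compared at passage 0 and later, had 2 falls among 6 genes and 3 adjusted over the list alone, TAGLN, an actin-binding protein, with a change of -0.31 ± 0.101 (adjusted p = 0.0295), and a mean of -0.14 (camera, adjusted p = 0.0661, and adjusted p = 0.548 with an estimated correlation).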
